A study of Schmidtea mediterranea with 18 samples.

How the data were processed

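PolyA RNA of regenerating trunk fragments was sequenced from animals given APC, Bcat (beta-catenin-1) or control RNAi, at days 1 to 6 after amputation. Per the labels' protocols, animals had 3 RNAi feeds and were amputated 3 days after the last one, and libraries were made with an Illumina TruSeq kit with polyA selection. Per the series' design text, RNA of 3 biological replicates was pooled before sequencing, so each of the 18 libraries is 1 pool per treatment and day. Most labels name trunk fragments and the treatment protocol names tail fragments; trunk is used here.

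The authors deposited raw read counts per transcript for 82955 SmedASXL transcripts, as whole numbers with no normalization. Per the submitters' processing notes, bcl2fastq 1.8.3, Bowtie2 2.2.4 and DESeq2 (version not given) were used, with no settings stated in the sources used here. The count table has 2 rows that name no transcript, total reads and unaligned reads, which were left out of library sizes and tests. Unaligned reads were 5.22% of all reads. In every library the transcript counts sum exactly to total minus unaligned reads, so each aligned read was counted once. How a read that fits several similar transcripts was placed is not given in the sources used here, so counts of near-identical transcripts are uncertain, and isoforms of 1 gene may be listed as separate transcripts. Strand use in counting is not given either.

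The second deposited table holds the authors' DESeq2 log2 fold changes and adjusted p-values for APC RNAi against Bcat RNAi over all time points. Per the file headers, it lists transcripts with an adjusted p-value of at most 0.05 and at least 20 counts per sample time point, and a negative log2 fold change means a higher level in Bcat RNAi. Of its 12115 transcripts, 9941 had at least 20 reads in each APC and Bcat RNAi library and 11880 had a mean of at least 20 over them.

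Samples were grouped by the treatment in the labels, and day was taken from the titles. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by treatment kept 36235 transcripts and left out 46720, which held 0.284% of the reads. Libraries were scaled with TMM factors. The quasi-likelihood test (glmQLFit, glmQLFTest) used all 18 libraries with day as a factor and treatment, which leaves 10 residual degrees of freedom, and tested APC RNAi and Bcat RNAi against control and against each other. A second model with day as a number tested treatment by day slopes and the slope of control, with 12 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all transcripts tested, with a threshold of 0.05. Abundances are given as CPM after TMM scaling, and differences at single days use log2 CPM with a prior count of 2. Folds against libraries with few reads depend on these settings, so read numbers are given where they are low.

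The replicate number of a library is its day, so day in the model is the replicate block. The labels give this pairing: libraries with the same number share a day. The correlation of same-day deviations from the treatment means ranged from 0.0656 to 0.324 between APC RNAi and control, from -0.0302 to 0.28 between Bcat RNAi and control and from -0.005 to 0.337 between the knockdowns, lowest at day 3 each time. No 2 libraries were identical, and the lowest chi-square per degree of freedom between any 2 was 5.95.

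The rule for named transcripts was set before the data were examined. Where transcripts carry no names, it takes at most 2 that rose and 2 that fell per comparison: those with the largest change among transcripts past the threshold, with a mean log2 CPM of at least 1 and, for comparisons of treatments, the same direction at all 6 days. For opposite changes it takes those with the largest smaller change. The gene lists set beforehand (positional, Wnt pathway, neural, eye, stem cell, muscle, gut, epidermal and others), the check of the RNAi targets and the list tests were not run, because the files do not pair identifiers with names and no reference was given.

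The edgeR steps were tested on simulated counts with the real means and library sizes for all 36235 transcripts. Changes and slopes were planted only in transcripts with a mean of at least 1 CPM. The shares called therefore do not cover transcripts below 1 CPM. For APC RNAi against control 88.1% of the 1.5-fold and 100% of the 2-fold changes were called, with 9 false calls, and for Bcat RNAi 97% and 100%, with 11. Of slopes differing by 0.2 log2 units per day 55% were called for APC RNAi and 62% for Bcat RNAi, and of those differing by 0.4, 95% for each. False slope calls were 9 for APC RNAi and 14 for Bcat RNAi. These slopes were exactly linear, with dispersions from the model with day as a factor. In the real slope test departures from a line add to the residuals, so these shares may be too high. A simulated shift with abundance in the APC RNAi libraries alone gave 7500 calls with TMM factors and 3 with loess offsets per library.

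Alternatives were RLE size factors, no count filter, a stricter filter (1 CPM in 6 libraries), no replicate block, only the 2 treatments compared, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), each day left out, days 3 to 6 only, a 2-fold threshold, log2 of the day, and split controls. Split controls set each knockdown against the controls of odd or even days only, using its own libraries of those same days. Chosen after seeing the data were loess offsets (span 0.3), TMM factors from transcripts of at least 4 CPM, only those 13059 transcripts, days 3, 4 and 6 only, a term for control days 2 to 6 with Bcat RNAi day 1, separate fits of the control and the knockdown libraries, the low-abundance share as a covariate, and single days of Bcat RNAi against control. Unchanged groups that share their controls were simulated 10 times, with all 18 libraries, controls included, drawn from the control means. Library measures were compared between treatments with exact sign-flip permutation tests over the 6 days. Figures were drawn with matplotlib 3.10.9.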

Results

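The series measured polyA RNA in regenerating trunk fragments of the planarian Schmidtea mediterranea, a flatworm that regrows missing tissue from stem cells (asexual strain CIW4). Animals were fed double-stranded RNA against apc, against beta-catenin-1 (here Bcat RNAi) or a control sequence. They were amputated and sampled daily from day 1 to day 6 after amputation. The apc protein promotes breakdown of beta-catenin, the effector of canonical Wnt signalling, so the 2 knockdowns act on opposite sides of the pathway. Each of the 18 libraries, 1 per treatment and day, was made from RNA pooled from 3 biological replicates. Errors given as SD are therefore over the 6 days of a treatment, and p-values measure how constant an effect was over the days, not how it varied between animals. Reads aligned to transcripts ranged from 41549185 to 58308153 per library, and averaged 50.4 M ± 5.2 for APC RNAi, 49.0 M ± 5.21 for Bcat RNAi and 52.0 M ± 4.13 for control RNAi (SD, n = 6 libraries each). The count table holds 82955 transcripts, of which 36235 had enough reads to be tested. The files do not pair transcript identifiers with gene names, so transcripts are given by identifier, at most 2 each way per comparison. The knockdown of apc and beta-catenin-1 themselves could not be read.

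APC RNAi against control asked which transcripts change when the brake on beta-catenin is reduced during regeneration. SmedASXL_013884 rose most among the transcripts eligible to be named, from 10.97 CPM ± 8.9 in control to 69.0 CPM ± 25.1 in APC RNAi (SD, n = 6). Its log2 fold change was 2.93 (SE 0.27, adjusted p = 2.11e-07, edgeR quasi-likelihood test), and it was higher at 6 of 6 days. SmedASXL_066371 rose from 1.47 CPM ± 1.64 to 7.31 CPM ± 3.03, with a log2 fold change of 2.73 (SE 0.32, adjusted p = 4.72e-06, edgeR). SmedASXL_018153 fell from 20.6 CPM ± 13.7 in control to 0.833 CPM ± 0.793 in APC RNAi, a log2 fold change of -4.61 (SE 0.38, adjusted p = 5.23e-08, edgeR). SmedASXL_008433 fell from 2.52 CPM ± 1.66 to 0.179 CPM ± 0.221, a log2 fold change of -3.87 (SE 0.4, adjusted p = 9.06e-07, edgeR), and had 49 reads in all 6 APC RNAi libraries together. Its log2 fold change was -4.46 without day 6. With a model term that set control days 2 to 6 and the Bcat RNAi day 1 library apart it was -5.38, and that of SmedASXL_018153 was -5.61.

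In the whole comparison 7644 transcripts were higher and 8370 lower in APC RNAi than in control (edgeR quasi-likelihood test, adjusted p under 0.05). Most of these changes were small: 99 of the higher and 1426 of the lower transcripts changed at least 2-fold. Direction differed by abundance class. Of 17974 transcripts with a mean below 1 CPM, 5546 were lower and 305 higher, with a median log2 change of -0.41. Of 2665 transcripts over 64 CPM, 2043 were higher and 53 lower, with a median log2 change of 0.25. Among transcripts of 2 CPM or more that changed at least 2-fold, the 47 higher ones had a median log2 difference of 1.14 at day 1 and 2.09 at day 6. The 50 lower ones stood at -1.01 at day 1, -1.73 at day 2 and -1.20 at day 6. The split moved with the scaling: 9890 higher and 6655 lower with RLE size factors, 4424 and 3689 with loess offsets that remove the shift with abundance, and 2981 and 13992 with TMM factors taken from transcripts of at least 4 CPM, which moved the median log2 change by -0.17. With the same term for control days 2 to 6 and Bcat RNAi day 1, 2616 were higher and 1502 lower. That term covers every control library but that of day 1. It thus overlaps with control against knockdown and can lower the number of calls by itself.

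**Figure D1:**
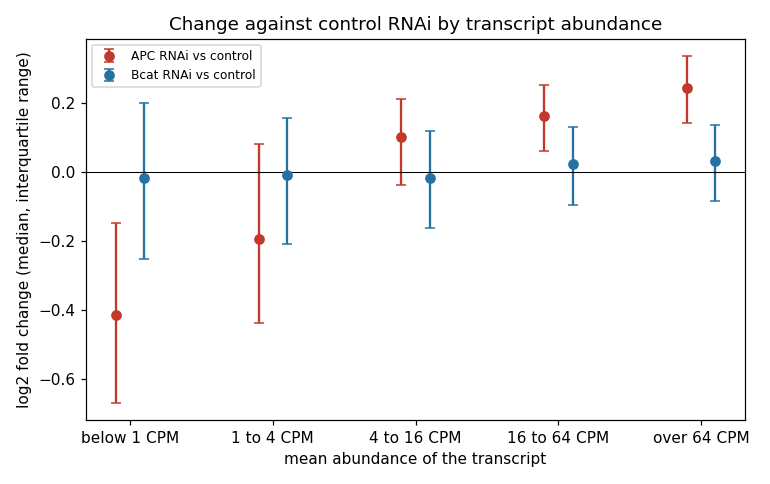
Log2 fold change against control RNAi (vertical axis) for tested transcripts in 5 classes of mean abundance in CPM (horizontal axis). Points are medians and bars interquartile ranges over transcripts, red for APC RNAi and blue for Bcat RNAi. The APC RNAi median goes from -0.41 below 1 CPM to 0.25 over 64 CPM, while the Bcat RNAi medians lie between -0.02 and 0.03.

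The same shift showed in the libraries as a whole. Transcripts below 1 CPM took 0.726% ± 0.13 of the reads in APC RNAi, 1.11% ± 0.138 in Bcat RNAi and 1.14% ± 0.171 in control (SD, n = 6). The APC RNAi share was below that of control at 6 of 6 days, with a mean difference of -0.413 percentage points (exact two-sided sign-flip permutation test over 6 days, p = 0.0312, the smallest that 6 days allow; 0.125 after Benjamini-Hochberg adjustment over 12 tests). Unaligned reads made up 4.88% ± 0.712 of the reads in APC RNAi and 5.43% ± 0.637 in control, and were lower in APC RNAi at 6 of 6 days (exact p = 0.0312, adjusted 0.125). At an equal depth of 40 M reads, 67550 ± 2899 transcripts were detected in APC RNAi and 73450 ± 1872 in control. Within control, the low-abundance share went from 0.869% at day 1 to 1.36% at day 6.

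**Figure D2:**
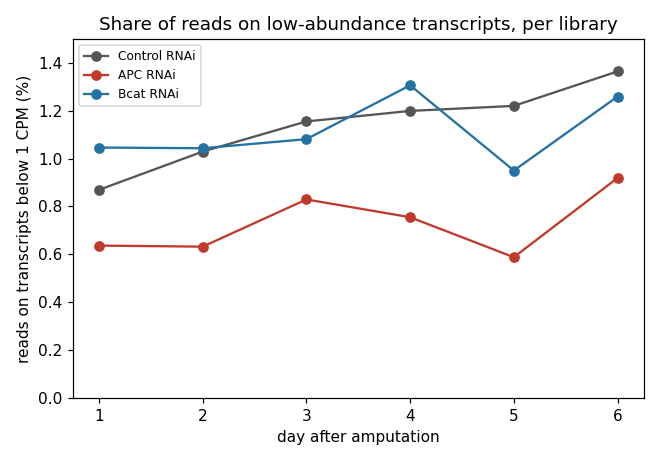
Share of each library's reads, in percent (vertical axis), on transcripts with a mean below 1 CPM, by day after amputation (horizontal axis). Each point is 1 pooled library, grey for control, red for APC and blue for Bcat RNAi. At each of the 6 days the APC RNAi library lies below the control library, and its values range from 0.588% to 0.919%.

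Bcat RNAi against control asked which transcripts change in regenerating fragments when beta-catenin-1 is targeted. Several abundant transcripts were nearly lost. Without gene names, the targeted transcript itself could be among them. SmedASXL_012097 fell from 87.5 CPM ± 45.3 in control to 0.412 CPM ± 0.55 in Bcat RNAi (SD, n = 6), a log2 fold change of -7.81 (SE 0.2, adjusted p = 2.99e-17, edgeR quasi-likelihood test), and of -8.46 without day 1. SmedASXL_048827 fell from 31.2 CPM ± 10.4 to 0.145 CPM ± 0.121, a log2 fold change of -7.75 (SE 0.16, adjusted p = 8.6e-19, edgeR). Both were lower at 6 of 6 days, including day 1. SmedASXL_058193 rose from 0.643 CPM ± 0.466 in control to 32.3 CPM ± 21.2, a log2 fold change of 5.52 (SE 0.32, adjusted p = 4.57e-11, edgeR), and its level in Bcat RNAi went from 8.42 CPM at day 1 to 66.2 CPM at day 6. SmedASXL_011884 rose from 17.9 CPM ± 6.5 to 125.2 CPM ± 51.2, a log2 fold change of 2.86 (SE 0.31, adjusted p = 7.18e-07, edgeR).

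In Bcat RNAi 3426 transcripts were higher and 4000 lower than in control, of which 236 and 608 changed at least 2-fold and 30 and 46 at least 8-fold. In APC RNAi 2 higher and 6 lower transcripts changed at least 8-fold. In Bcat RNAi the median log2 change was within 0.04 of 0 in all 5 abundance classes. Among transcripts of 2 CPM or more that changed at least 2-fold, the 131 lower ones had a median log2 difference of -1.17 at day 1, -1.71 at day 2 and -1.45 at day 6, and 102 of them were lower at all 6 days. The 54 higher ones stood at 0.76 at day 1 and 1.47 at day 6, and 52 were higher at all 6 days. With no replicate block, that is with day left out of the model, 1566 transcripts were higher and 2560 lower. Without day 3, 2155 were higher and 2634 lower. With the term that set control days 2 to 6 and Bcat RNAi day 1 apart, 1106 were higher and 1499 lower. Here too the overlap of this term with control can lower the number of calls.

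Because the knockdowns act on opposite sides of beta-catenin, the comparisons with control were set against each other. SmedASXL_012639 was ordered APC RNAi over control over Bcat RNAi at every day, with means of 27.1 CPM ± 2.23, 7.43 CPM ± 0.703 and 0.658 CPM ± 0.166 (SD, n = 6). Its log2 fold changes against control were 1.87 (SE 0.08, adjusted p = 1.63e-12) in APC RNAi and -3.49 (SE 0.11, adjusted p = 8.4e-16) in Bcat RNAi (edgeR). SmedASXL_007760 had the same order, with 22.7 CPM ± 2.44, 6.67 CPM ± 1.32 and 0.127 CPM ± 0.0307. The reverse order was held by SmedASXL_050373, with 0.425 CPM ± 0.305 in APC RNAi, 2.42 CPM ± 0.717 in control and 13.5 CPM ± 5.17 in Bcat RNAi. SmedASXL_080365 had 0.139 CPM ± 0.162, 0.823 CPM ± 0.664 and 4.96 CPM ± 2.09 in the same order of treatments, the APC RNAi mean resting on 36 reads.

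In total 1251 transcripts were higher in APC RNAi and lower in Bcat RNAi, where independent lists of these sizes would share 843.8. Another 504 were lower in APC RNAi and higher in Bcat RNAi, against 791.4. This second overlap turned with the scaling: it was 902 against 401.9 with loess offsets, 338 against 606.1 with RLE size factors and 1210 against 1277.4 with TMM factors from transcripts of at least 4 CPM. The first overlap was 811 against 543.9, 1433 against 1045.6 and 777 against 378.2 in the same order. Transcripts higher in both numbered 957 against 722.7, and those lower in both 1208 against 924; with TMM factors from transcripts of at least 4 CPM the latter were 1685 against 1775.1. Both comparisons use the same control libraries, which favours changes in the same direction, so independent lists do not give the overlap expected without an effect. With APC RNAi and control of the odd days and Bcat RNAi and control of the even days, 3 libraries of each, 101 were higher and 255 lower in both. The other way round they were 194 and 53. These fits use fewer libraries of every treatment and read the knockdowns on different days. The lower counts can therefore not be put down to unshared controls alone. The counts also moved with the libraries and the model. Without day 4 the first overlap was 744. The second was 327 without day 2, 326 without day 3 and 291 without day 4, and transcripts higher in both were 553, 617 and 578 without days 3, 4 and 6. With day left out of the model the overlaps were 530, 140, 245 and 786. Among all 36235 tested transcripts, called or not, the order APC RNAi over control over Bcat RNAi held at all 6 days for 1150. The reverse order held for 441. Both counts were taken with TMM factors only, so their split may move with the scaling as the overlaps did. Of the 96 transcripts of at least 4 CPM that fell at least 2-fold in Bcat RNAi, a set chosen after its values were seen, 63 (65.6%) were higher in APC RNAi than in control, 15 were lower and 18 were not called, where 52.4% of all 13059 transcripts of at least 4 CPM were higher. Of the 35 that rose at least 2-fold in Bcat RNAi, 19 (54.3%) were lower in APC RNAi, 3 were higher and 13 were not called, where 6.47% of the 13059 were lower. With loess offsets 50 of 95 (52.6%) that fell were higher in APC RNAi, against 17.9% of the 13059, and 20 of 36 (55.6%) that rose were lower, against 15.8%.

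The log2 fold changes of the 2 knockdowns correlated with r = 0.163 across transcripts, which are not independent replicates. Simulated groups with no effect, compared with a shared set of control libraries that was simulated as well, gave a mean of 0.478. A change in 1 knockdown alone also lowers the correlation, so a value below the simulated one does not by itself show opposite changes. The simulation held no shift with abundance and no effect of day. The covariance over all tested transcripts was 0.0304, above the simulated 0.0169. For transcripts of at least 4 CPM the correlation was -0.148 against a simulated 0.496, and the covariance -0.0118 against 0.0029. With odd-day libraries for 1 knockdown and its controls and even-day libraries for the other, the covariance over 4 CPM was -0.0127 both ways. Over all tested transcripts it was 0.00993 and 0.0249 in these smaller fits. The correlation was -0.044 when only transcripts with at least 1 CPM in at least 6 libraries were kept. The term for control days 2 to 6 and Bcat RNAi day 1 was chosen after the data were seen. It overlaps with control against knockdown, so it can remove shared calls by its build. With this term the number lower in both knockdowns was 52. That does not tell how many of the 1208 stem from a difference between libraries. Without day 1 the number lower in both knockdowns was 1896. It was 709, 641, 771, 755 and 779 without days 2, 3, 4, 5 and 6.

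**Figure D3:**
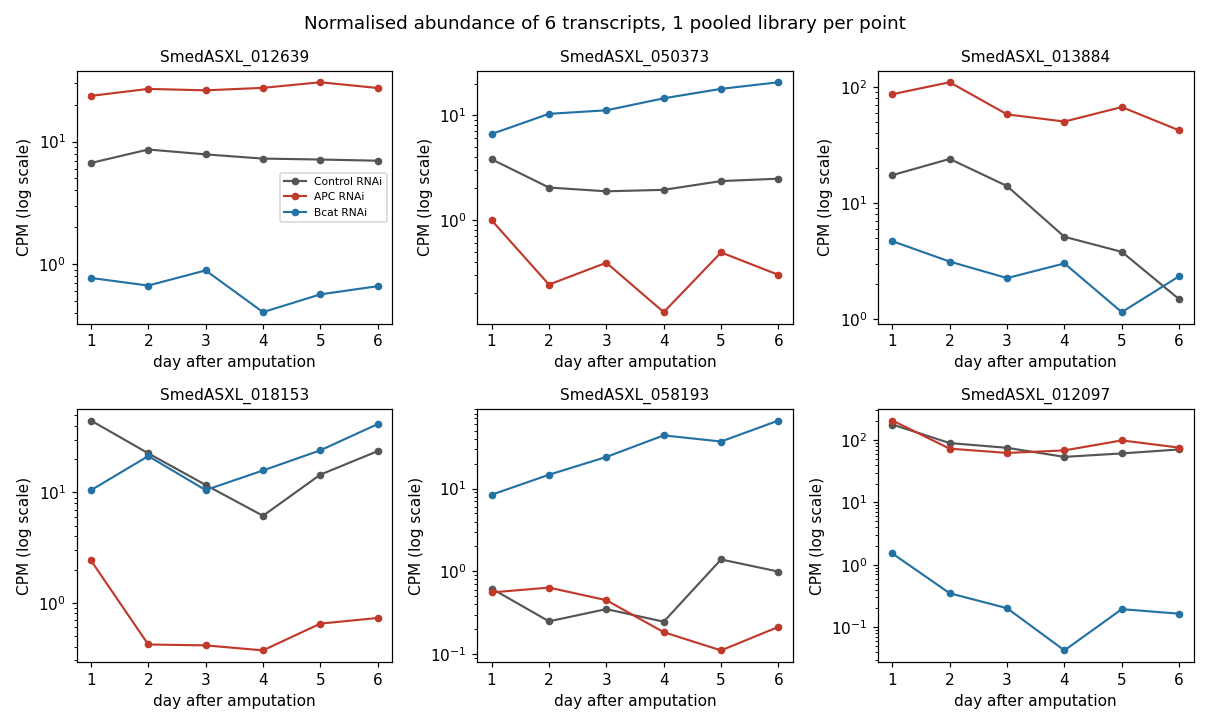
Normalised abundance in CPM (vertical axis, log scale) of 6 transcripts by day after amputation (horizontal axis). Each point is 1 pooled library, with lines joining the days of control (grey), APC (red) and Bcat RNAi (blue). SmedASXL_012639 and SmedASXL_050373 keep opposite orders of the treatments at every day, and SmedASXL_012097 stays at or below 1.52 CPM in Bcat RNAi.

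APC RNAi against Bcat RNAi, the comparison in the authors' deposited table, was tested in the same model of all 18 libraries. Among the transcripts eligible to be named, SmedASXL_048827 was highest in APC RNAi relative to Bcat RNAi, at 47.3 CPM ± 18.5 against 0.145 CPM ± 0.121 (SD, n = 6), a log2 fold change of 8.34 (SE 0.16, adjusted p = 9.16e-20, edgeR quasi-likelihood test). SmedASXL_006770 stood at 270.6 CPM ± 97.3 against 1.16 CPM ± 1.59, a log2 fold change of 8.05 (SE 0.26, adjusted p = 3.64e-16, edgeR), and of 8.78 without day 1. Among those eligible, SmedASXL_058193 was lowest, at 0.359 CPM ± 0.218 against 32.3 CPM ± 21.2, a log2 fold change of -6.31 (SE 0.36, adjusted p = 1.53e-11, edgeR). SmedASXL_011587 was also lower, at 0.148 CPM ± 0.101 against 6.6 CPM ± 0.818, a log2 fold change of -5.48 (SE 0.18, adjusted p = 4.15e-16, edgeR), and stood between them in control at 2.04 CPM ± 0.326. Altogether 8355 transcripts were higher and 9412 lower in APC RNAi than in Bcat RNAi, 482 and 1169 of them at least 2-fold and 70 and 47 at least 8-fold. Among transcripts of 2 CPM or more that differed at least 2-fold, 228 of 231 higher and 110 of 113 lower ones differed the same way at all 6 days. With TMM factors from transcripts of at least 4 CPM, 5063 were higher and 14785 lower, and with loess offsets 6988 and 5913. With the 12 knockdown libraries alone, 8488 were higher and 8849 lower.

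The authors' deposited table lists 12115 transcripts, 6229 with a higher level in APC RNAi and 5886 with a higher level in Bcat RNAi. Of these 12008 (99.1%) were called here in the direction of the authors' deposited table, 0 in the opposite direction, and 107 were not called. A further 5759 transcripts called here were not in it. Across the listed transcripts the log2 fold changes correlated with r = 0.974 with those found here (transcripts are not independent replicates). Each named transcript that is listed has a smaller absolute value there: SmedASXL_058193 has a log2 fold change of -2.54 and SmedASXL_006770 one of 2.01, against -6.31 and 8.05 here. The DESeq2 fit run here gave -6.21 and 8.53. The settings of the authors' DESeq2 run are not given, so the deposited values may not be the same measure. SmedASXL_007760 has the largest value in the authors' deposited table, 6.45. SmedASXL_012097, with a log2 fold change of 7.94 between the knockdowns here (SE 0.2, adjusted p = 5.14e-18, edgeR), is not in the authors' deposited table. Its lowest Bcat RNAi library held 2 reads, but so did that of SmedASXL_048827, which is listed, and the 6 Bcat RNAi libraries held 4 to 9 reads of SmedASXL_007760.

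Slopes over days asked which differences from control grew or shrank with time. SmedASXL_068695 went down over the days in Bcat RNAi, from 46.2 CPM at day 1 to 0.165 CPM at day 6, and in control only from 54.3 to 20.8 CPM. Its slope differed from that of control by -1.22 log2 units per day (SE 0.15, adjusted p = 0.000536, edgeR quasi-likelihood test). The slope of SmedASXL_013733 differed by -0.62 (SE 0.1, adjusted p = 0.00672, edgeR), with a Bcat RNAi level at or below 2.87 CPM at every day. SmedASXL_011882 went the other way, by 0.45 log2 units per day (SE 0.08, adjusted p = 0.0439, edgeR), from 52.7 CPM at day 1 to 168.4 CPM at day 6 in Bcat RNAi. SmedASXL_053050 differed by 0.44 (SE 0.07, adjusted p = 0.00988, edgeR). SmedASXL_066371 went from 12.03 CPM at day 1 to 4.07 CPM at day 6 in APC RNAi, and in control from 3.94 CPM to 0.018 CPM, 1 read. Its slope difference was 0.9 log2 units per day (SE 0.12, adjusted p = 0.00124, edgeR). SmedASXL_018601 stood at 18.7 and 21.7 CPM at days 1 and 2 in APC RNAi and between 101.2 and 138.3 CPM from day 3, with a slope difference of 0.67 (SE 0.12, adjusted p = 0.0362, edgeR). The only transcript called with a slope below that of control in APC RNAi was SmedASXL_017870, with a difference of -0.24 (SE 0.04, adjusted p = 0.0245, edgeR).

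The slope over days differed from that of control for 13 transcripts upward and 1 downward in APC RNAi, and for 7 upward and 5 downward in Bcat RNAi (edgeR). At an unadjusted p under 0.05 there were 2920 and 2130 transcripts. These counts rest on few libraries: leaving out 1 day at a time gave between 3 and 31 upward differences in APC RNAi and between 6 and 26 in Bcat RNAi, and the DESeq2 Wald test gave 44 and 23. Of 13 alternative fits, SmedASXL_017870 lost its call in 8, SmedASXL_018601 in 7 and SmedASXL_011882 in 6. SmedASXL_053050 and SmedASXL_013733 lost it in 2 each, and SmedASXL_066371 and SmedASXL_068695 in 1 each. Each of the named slopes lost its call in at least 1 alternative: without day 1 the adjusted p was 0.947 for SmedASXL_018601, 0.17 for SmedASXL_017870, 1 for SmedASXL_011882, 0.404 for SmedASXL_053050 and 0.308 for SmedASXL_013733, and with log2 of the day it was 0.0948 for SmedASXL_066371 and 0.209 for SmedASXL_068695 (edgeR).

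The trend over days after amputation was read in the control libraries. The series has no libraries of uncut animals, so regeneration cannot be told apart from time since the last RNAi feed. SmedASXL_010173 rose from 3 CPM at day 1 to 12.7 CPM at day 6, by 0.48 log2 units per day (SE 0.06, adjusted p = 6.28e-05, edgeR quasi-likelihood test). SmedASXL_008433 rose by 0.52 log2 units per day (SE 0.1, adjusted p = 0.003, edgeR), from 1.06 to 4.49 CPM; the DESeq2 Wald test gave it an adjusted p of 0.0611. SmedASXL_006360 fell by 1.31 log2 units per day (SE 0.23, adjusted p = 0.000941, edgeR), from 45.2 to 1.27 CPM, and SmedASXL_066371 fell by 1.16 (SE 0.09, adjusted p = 1.01e-07, edgeR). In all 1064 transcripts rose and 2622 fell with day in control. Their direction went with abundance in the opposite sense to APC RNAi: over 64 CPM 48 rose and 734 fell, while below 1 CPM 295 rose and 112 fell. The split moved with the scaling here too, to 1238 rising and 1576 falling with loess offsets and 2185 and 1275 with TMM factors from transcripts of at least 4 CPM. Without day 1, 324 rose and 317 fell.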

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

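The bound for the background explanation was set before its result was seen; the tests on splits, depth, composition and the difference between libraries were written down afterwards.

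In APC RNAi, transcripts below 1 CPM were lower relative to those over 64 CPM than in control at every day, by a median of 0.36 to 0.98 log2 units. A lower depth of the APC RNAi libraries is argued against by the count of transcripts at equal depth, which was lower by a mean difference of -5896 (SD 2350, n = 6 days). A few abundant transcripts taking more of the reads would shift all others alike, but the median log2 change below 1 CPM lay at -0.61 (SD 0.216 over days) relative to that over 64 CPM. Fewer background reads, the same number per transcript, would cost transcripts of 1 to 4 CPM about as many CPM as those below 1 CPM. They lost 3.35 times as many (SD 0.182) with TMM factors from transcripts of at least 4 CPM. That scaling was chosen after the data were seen and lowers the APC RNAi libraries. The ratio was not computed with the main TMM factors, so it argues against such background under that scaling only. Background that scales with a transcript's length or level, a difference in RNA or library preparation, and an effect of APC RNAi on the make-up of the tissue stay open, untested. The labels give 1 library kit and record no difference in preparation between treatments, and the share of unaligned reads was also lower at 6 of 6 days.

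A set of 492 transcripts was at least 2-fold lower in both knockdowns on days 2 to 6, 441 of them with a mean below 1 CPM. Day 1 was not used to choose them, and there 85.6% were higher in the Bcat RNAi than in the control library, against 51% of all tested transcripts. An exchange of the 2 day 1 libraries is argued against by 21 transcripts at least 8-fold lower in Bcat RNAi on days 2 to 6, all 21 of which were lower at day 1 too, with a median log2 difference of -3.99. The same response to either RNAi stays open: the median log2 difference of Bcat RNAi from control at day 1 was 0.63 (interquartile range 0.18 to 1.01), but this is 1 library pair. A response that starts after day 1 would explain the lack of a fall in Bcat RNAi at day 1, but not the higher level. In APC RNAi 366 of the 492 were already lower than in control at day 1, where low-abundance transcripts as a class were lower. A difference between libraries that crosses the treatments may also lie behind many of these transcripts: their median was 0.288 CPM in control and 0.424 CPM in Bcat RNAi at day 1, and 0.534 to 0.584 CPM against 0.201 to 0.277 CPM on days 2 to 6. What distinguishes these libraries is not recorded in the labels.

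For the comparisons of treatments, chance in how the libraries were parted is argued against, though 1 of 39 is the smallest share these splits allow. The splits do not test chance differences between the groups of animals behind the pools. Of 39 splits of the 12 libraries of APC RNAi and control into 6 and 6, only the real one, 1 split, gave as many as its 15553 transcripts; the highest other gave 12773 and parted 5 of the 6 APC RNAi libraries from 5 of the 6 control libraries. For Bcat RNAi against control the real split gave 7579 and the highest of the others 2112 (1 of 39 as large), and for APC RNAi against Bcat RNAi 17337 and 9777 (1 of 39). Among the 32 splits that swap the treatments within days, which part as many pairs, the highest others gave 451, 2397 and 7 transcripts, each with the libraries of day 1 exchanged. For the slopes these splits do not decide on chance. With the real one, 5 of 32 gave as many transcripts as the 18 of APC RNAi and 4 of 32 as many as the 22 of Bcat RNAi, with highest others of 6949 and 1613. The 4 and 3 others as large each exchanged an unbroken run of the last days, which turns the constant difference between treatments into a slope. The 26 splits that exchanged other days gave at most 6 and 2 transcripts, but there the same difference adds to the residuals. These counts come from fits of the 12 libraries alone.

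In the slope test on all libraries the effect differed by day for 7 named transcripts, each of which lost its call in at least 1 alternative: SmedASXL_066371 (0.9 log2 units per day), SmedASXL_018601 (0.67) and SmedASXL_017870 (-0.24) in APC RNAi, and SmedASXL_053050 (0.44), SmedASXL_011882 (0.45), SmedASXL_013733 (-0.62) and SmedASXL_068695 (-1.22) in Bcat RNAi.

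Single libraries stood far from the other 5 of their treatment in 13 of 84 groups looked at, where chance would mark about 4.2. Of the 13, 12 were day 1 values of named transcripts, and days are a time course rather than replicates. In APC RNAi the most abundant transcript took 13.7% of the reads at day 5, against 10.1% to 10.8% at the other days. SmedASXL_012097 was highest at day 1 in all 3 treatments, at 204.6 CPM in APC RNAi, 176.5 CPM in control and 1.52 CPM in Bcat RNAi. SmedASXL_048827 reached 83.6 CPM in APC RNAi and 0.384 CPM in Bcat RNAi at day 1. In Bcat RNAi at day 1, SmedASXL_006770 stood at 4.35 CPM, SmedASXL_013733 at 2.87 CPM and SmedASXL_006360 at 60.7 CPM. SmedASXL_018153 stood at 2.42 CPM in APC RNAi at day 1. SmedASXL_080365 stood at 0.461 CPM in APC RNAi and 2.17 CPM in control, and SmedASXL_050373 at 3.8 CPM in control, each at day 1.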

How the results depend on the processing

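Loess offsets, TMM factors or tests limited to transcripts of at least 4 CPM, days 3, 4 and 6 alone, and the term for control days 2 to 6 with Bcat RNAi day 1 were chosen after the data were seen. That term overlaps with control against knockdown, so calls can also be lost through the overlap. Named transcripts kept direction and call in 490 of 518 alternative fits; 28 lost the call, all in slopes or the day trend, and 0 reversed. Fold sizes moved more. With the library term, log2 fold changes against control were -5.61 for SmedASXL_018153, -5.38 for SmedASXL_008433, -3.57 for SmedASXL_080365 and -3.3 for SmedASXL_050373 in APC RNAi, and 4.68 for SmedASXL_058193, 2.11 for SmedASXL_011884, 1.82 for SmedASXL_080365 and 1.79 for SmedASXL_050373 in Bcat RNAi. For days 3 to 6 SmedASXL_066371 stood at 3.66 in APC RNAi (3.42 with DESeq2), SmedASXL_012097 at -8.72 and SmedASXL_080365 at 3.39 in Bcat RNAi, and SmedASXL_006770 at 9.21, SmedASXL_058193 at -7.39 and SmedASXL_011587 at -6.12 between the knockdowns. The gene list tests were not run. The cause of a move was not tested except where the setting itself tests fewer transcripts (the filters, only 4 CPM and above), asks for more (the 2-fold threshold) or uses fewer libraries (days, split controls).

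Counts are given as higher, then lower. For APC RNAi against control the 2-fold threshold gave 99 and 1426, the stricter filter 4640 and 4693, DESeq2 4547 lower, loess offsets 4424 and 3689, TMM factors from 4 CPM and above 2981 and 13992, only those transcripts 2646 and 2757, days 3, 4 and 6 gave 4936 and 4246, and the library term 2616 and 1502. For Bcat RNAi against control the threshold gave 236 and 608, no replicate block 1566 and 2560, and the library term 1106 and 1499. For APC RNAi against Bcat RNAi the threshold gave 482 and 1169, DESeq2 5361 lower, loess 5913 lower, TMM factors from 4 CPM and above 5063 and 14785, only those transcripts 4262 and 4110, and days 3, 4 and 6 gave 5757 lower.

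For changes in both knockdowns, the values are APC higher with Bcat lower, APC lower with Bcat higher, both higher and both lower. No replicate block gave 530, 140, 245 and 786, and ended no call of a named transcript. The library term gave 360, 138, 133 and 52, odd-day controls for APC 165, 100, 101 and 255, even-day controls 414, 130, 194 and 53, and only 4 CPM and above 770, 966, 484 and 518. Loess gave 811, 902 and 544 for the first 3, TMM factors from 4 CPM and above 777, 1210 and 431. The second was 314 with no filter, 897 with the stricter filter and 266 with DESeq2; both lower was 740 with the stricter filter and 692 with DESeq2. Days 3, 4 and 6 gave 728 for the first and 567 for both higher. The correlation of log2 fold changes reversed to -0.044 with the stricter filter and to -0.144 with only 4 CPM and above; it was 0.379 with no filter, 0.3 for days 3 to 6, 0.288 for days 3, 4 and 6, 0.105 with the library term and 0.041 with odd-day controls for APC.

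For slopes, given as up and down, no filter gave 88 and 4 in APC RNAi and 116 and 11 in Bcat RNAi. In APC RNAi the stricter filter gave 2 and 0, DESeq2 44 and 2, log2 of the day 31 up, and loess and TMM factors from 4 CPM and above 2 and 0 each. In Bcat RNAi DESeq2 gave 23 up and log2 of the day 15 up. The day trend had 699 up with RLE, 468 and 1654 with no filter, 1758 up with the stricter filter, 1576 down with loess, and 2185 and 1275 with TMM factors from 4 CPM and above.

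Leaving out 1 day at a time, the lowest and highest counts were 6224 to 7801 higher and 5590 to 8868 lower for APC RNAi, 2155 to 3732 and 2634 to 4745 for Bcat RNAi (lowest without day 3), 7221 to 8396 and 6981 to 9022 for APC against Bcat RNAi. Changes in both ranged over 744 to 1246, 291 to 604, 553 to 1107 and 641 to 1896 (highest without day 1), and the correlation over 0.133 to 0.275. Slopes ranged over 3 to 31 up and 0 to 2 down in APC RNAi and 6 to 26 up and 1 to 12 down in Bcat RNAi. The day trend ranged over 324 to 1608 up and 317 to 4336 down, lowest without day 1 and highest without day 5.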

Other observations

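Transcripts that changed over the days after amputation in control also differed between the knockdowns. Their choice leans on day 1: without it far fewer transcripts rose or fell in control, as given above. No reading of sets chosen without day 1 is given. They were chosen by the day trend of the control libraries at 2 CPM or more and read between APC RNAi and Bcat RNAi in the model of all 18 libraries, with loess offsets that remove the shift with abundance. Of 653 transcripts that rose over days in control, 507 (77.6%) were lower in APC RNAi than in Bcat RNAi and 27 (4.13%) higher, against 28.3% and 31.4% of all 15203 such transcripts. Of 2461 that fell over days in control, 1226 (49.8%) were higher in APC RNAi and 256 (10.4%) lower. With the transcripts chosen from the day trend under loess offsets instead, 830 of 1152 rising ones (72%) were lower in APC RNAi and 742 of 1276 falling ones (58.2%) higher. The first 2 tests on the falling transcripts and the test by day on the rising ones were set before their results were seen; the other tests on the rising ones, and those in fits that share no library, were written afterwards.

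The median log2 difference of APC from Bcat RNAi was -0.43 for the rising transcripts, below all of 10000 random lists matched on abundance (middle 95%: 0 to 0.05), and 0.12 for the falling ones, above all of them (0.01 to 0.03). The same control libraries entering the choice and the reading are argued against by fits that share no library, with the day trend from the 6 control libraries and the difference from the 12 others: the medians were -0.39 for 1268 rising transcripts (random lists: 0 to 0.04) and 0.13 for 3287 falling ones (0 to 0.02). Against control, the rising transcripts had a median of -0.27 in APC RNAi and 0.17 in Bcat RNAi, where the random lists gave 0.02 and 0.01. Here 291 of them were higher in Bcat RNAi than in control and 39 lower. This argues against the property of the APC RNAi libraries behind the shift with abundance as the whole source for the rising transcripts, since the low-abundance shares of Bcat RNAi and control differed by a mean of only -0.0252 percentage points (SD 0.16). On days 3, 5 and 6 the Bcat RNAi share differed from that of control by -0.074, -0.27 and -0.105 percentage points, against a mean of -0.413 in APC RNAi. Such shares would lower these transcripts, though less than in APC RNAi. Their medians were instead 0.28, 0.11 and 0.08 above control, a mean of 0.16 (SD 0.108), where the middle 95% of the random lists ended at 0.04 or lower. The control libraries enter both the choice and this reading, which favours higher values on early days and lower ones on late days. The fits that share no library do not cover Bcat RNAi against control. With the share as a covariate the median stayed at 0.17, but with such equal shares the covariate had little to remove. A dependence on beta-catenin signalling stays open for them. For the falling transcripts it cannot be told apart from that property: their median in Bcat RNAi against control was 0 (421 higher and 468 lower) and differed from the random lists by 0.01, too little to decide, although the bound set beforehand asked only for a rank among the lists. In APC RNAi 1002 of them were higher than in control and 37 lower. Transcripts are not independent, so the rank among random lists describes these libraries only.

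Among transcripts that differed at least 8-fold between the knockdowns, 50 of the 70 higher in APC RNAi and 27 of the 47 higher in Bcat RNAi are in the authors' deposited table. Each of the 20 and 20 others had under 20 reads in at least 1 APC or Bcat RNAi library, but so had 35 and 20 of those listed. Most of the others were of low abundance: of the large changes at 2 CPM or more, 1 of 33 and 0 of 17 were not listed.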
